A study of Mus musculus with 10 samples.

How the data were processed

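Gene expression was measured in 10 mouse teratomas, each hybridised to its own 1-colour Affymetrix array. Per the labels, the tumours grew from Vhl-null J1 embryonic stem cells that expressed a human VHL cDNA, and they formed under the skin of female nude mice. There were 3 genotypes: 3 arrays with wildtype VHL, 3 with R167Q and 4 with P81S. The study design states that the 4 P81S arrays are 2 replicates of each of 2 clones, and the labels do not say which arrays share a clone. RNA was isolated from frozen tumour with a column kit, copied from an oligo(dT) primer, transcribed in vitro and labelled with biotin, per the labels' protocols.

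The deposited values were log2 expression values with 1 value per probe set and array, and they ran on the same scale in every array. The submitters' processing notes name RMA and Partek without versions or roles. RMA ordinarily corrects background, sets all arrays to 1 distribution and summarises probes into a log2 value, and no source used here states which of these steps were run or with which settings. Scanner files were not used here, so the signal over background of single probes is unknown, and the number of arrays limits the precision. Folds are ratios of deposited values, and no bound was set for transcripts near the floor. Array medians over all 35556 probe sets lay between 6.97 and 7.11 log2. Setting arrays to 1 distribution, if that was done, removes any change in total RNA. Each difference is therefore read as relative to the other transcripts of the same array.

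Probe sets were named from the platform annotation, with symbols looked up by Entrez number in a RefSeq gene table of assembly GRCm38.p6, which also gave each gene's chromosome. The 6612 probe sets with the lowest numbers, a run without annotation, were taken as the array's control block and left out. The median of this block is not a measured background. Of the 28944 probe sets outside it, 21218 were paired with 1 gene, 1881 with several genes and 5845 with no listed gene. Only the class with 1 gene was tested gene by gene. Entrez numbers matched for 21185 of the 21218, and 0 symbols needed an update. Each of 18820 genes was represented by its probe set with the highest mean over the 10 arrays; 1386 genes had a choice between several. Probe sequences were not used here, so signal shared between members of a gene family cannot be separated. All 10 value columns were used and 0 were left out.

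All 10 arrays entered 1 linear model with 3 group means, fitted with limma 3.58.1 (lmFit and eBayes with a variance trend, two-sided) in R 4.3.3, with statmod 1.5.0 for robust and random-block fits. The model had 7 residual degrees of freedom and a prior of 3.85. P81S was compared with wildtype, R167Q with wildtype, P81S with R167Q, and P81S with the average of the other genotypes' means. P-values were adjusted by the Benjamini-Hochberg method over the 18820 genes of a contrast, and a gene is called at an adjusted p under 0.05. Errors beside a log2 difference are standard errors from the model, and errors beside a group mean are SDs. No source says that tumours of a genotype came from separate cultures or animals, and each genotype stands for few cell clones. The p-values therefore measure only the spread between these teratomas, and a difference between clones counts as a difference between genotypes.

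There were 33 gene lists with 785 entries, of which 716 were measured. They cover metabolism, cell death, DNA damage, hypoxia, stress responses, pluripotency, tissues and blood cells that a teratoma or its host can hold, and transcripts of the donor's Y chromosome and of the host's inactive X. The 31 lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists of a contrast, and again with a correlation estimated for each list. Measured genes in more than 1 list numbered 7. For Xist and for the mean of 3 Y-linked transcripts, group means were compared with an exact two-sided permutation test.

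Named genes followed a rule. Vhl was named first, then, among called genes whose groups' arrays did not overlap, up to 10 with the largest rise and 10 with the largest fall in each contrast. Up to 3 genes of each list with the smallest p, Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty completed the rule, and Ddx3y was not analysed here. Genes outside the rule are said to be so where they appear. The comparisons, tests, lists, rule and alternatives listed next were chosen before the data were examined. The alternatives were another normalization, median centring, leaving out dim genes, averaging a gene's probe sets, testing all probe sets, other variance models, only the compared groups in the model, array weights, the replicate number as a block, each possible pairing of the P81S clones as a random block, Xist as a covariate, other list tests and leaving out each array in turn. Alternatives without the genes of chromosomes 8, 11 and Y, and without pairs of P81S arrays, were added after the data had been seen.

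The model was tested on simulated data drawn from the mean and residual SD of each of 18820 genes in 5 rounds. For P81S against wildtype it recovered 21.1%, 67.8% and 93.8% of genes shifted by 0.5, 1 and 2 log2, with 5.46% false calls. For R167Q against wildtype these shares were 18.6%, 70.6% and 95.1%, with 5.89% false calls. With no list shifted, 0 of 31 lists were called. With glycolysis shifted by 0.5 log2, 1 list was called, glycolysis itself. Genes were drawn independently of each other, whereas the estimated correlation in the data was, for example, 0.89 for the cell cycle list. The simulation therefore does not show how often camera calls lists of correlated genes by chance. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.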

Results

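Teratomas, tumours of mixed tissue that pluripotent cells form in a host animal, were profiled to ask how 2 mutant forms of the tumour suppressor VHL differ from the wildtype protein. The series title ties the P81S form to trichloroethylene exposure and names metabolism, apoptosis and the ATM branch of the DNA damage response as its subjects. VHL is the substrate-binding part of a ubiquitin ligase that marks hypoxia-inducible factors for destruction in the presence of oxygen. The 10 arrays comprised 4 P81S, 3 wildtype and 3 R167Q teratomas. The labels describe the P81S tumours as resistant to apoptosis and the wildtype and R167Q tumours as apoptotic. Each array gave log2 expression values for 18820 genes, with a median of 6.97 to 7.11 log2 over all probe sets.

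Replicates of wildtype and of R167Q resembled each other closely, and those of P81S less so. Across probe sets, which are not independent replicates, arrays of a group correlated with r of 0.973 to 0.991 in P81S, 0.990 to 0.994 in wildtype and 0.989 to 0.990 in R167Q, and no pair was identical. Between groups, r was 0.935 to 0.971 for P81S with wildtype, 0.951 to 0.984 for P81S with R167Q, and 0.982 to 0.990 for wildtype with R167Q. P81S replicate 2 correlated more closely with R167Q replicate 2 (r = 0.984) than with P81S replicate 1 (r = 0.973). The first principal component held 58.6% of the variance, and the 4 P81S arrays stood at 35.5 to 63.5 on it against -52.2 to -8.41 for the other 6 arrays. The second held 15.3%, and P81S replicate 1 stood apart on it at 54.9. List means in that array were 9.30 log2 for squamous epithelium, 9.08 for gut and glandular epithelium and 10.04 for extracellular matrix, against 6.44 to 6.95, 7.14 to 7.77 and 8.41 to 8.82 in the other P81S arrays.

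**Figure D1:**
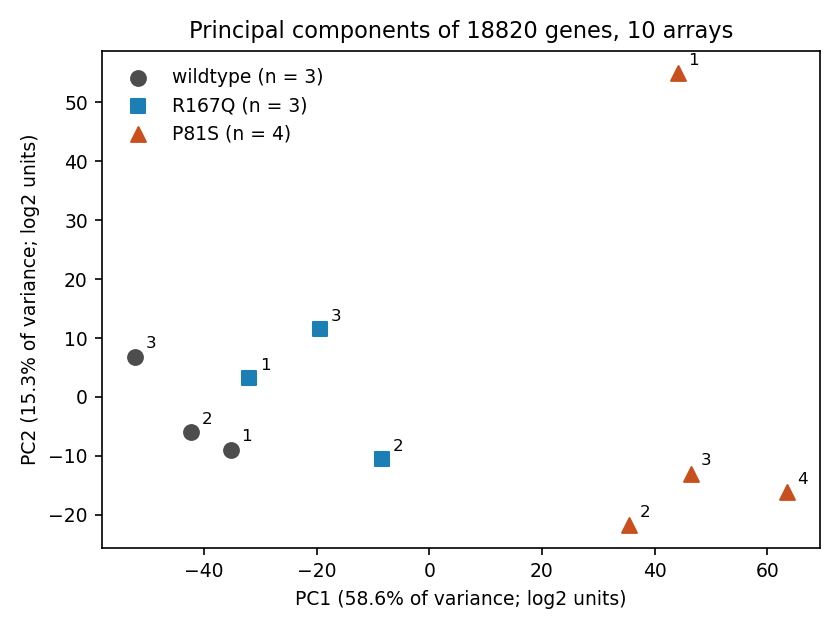
Scores of the 10 arrays on the first and second principal components of the log2 values (axes in score units, with the share of variance), 1 point per array, coloured by genotype. P81S arrays lie at 35.5 to 63.5 on the first component and the other arrays below -8.4.

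The targeted gene, mouse Vhl, read 8.49, 8.78, 8.53 and 8.90 log2 in P81S replicates 1 to 4, 6.94, 6.95 and 6.85 in wildtype replicates 1 to 3, and 6.83, 6.93 and 7.21 in R167Q replicates 1 to 3. Its mean was 8.67 ± 0.20 log2 (SD, n = 4) in P81S, 6.91 ± 0.05 (SD, n = 3) in wildtype and 6.99 ± 0.20 (SD, n = 3) in R167Q. These levels were higher than those of 60.8%, 36.6% and 36.8% of genes in the same groups. No source used here says which part of mouse Vhl was disrupted, whether the probes lie in it, or whether they bind the human transgene. A probe outside the deleted part checks nothing, so these values are no check of the labels.

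Y-linked transcripts, which can come only from the male J1 donor cells, were low in all 3 wildtype teratomas. The mean of Eif2s3y, Kdm5d and Uty was 4.47 ± 0.22 log2 (SD, n = 3) in wildtype, 8.95 ± 0.38 (SD, n = 4) in P81S and 9.34 ± 0.20 (SD, n = 3) in R167Q. The exact permutation test gave p = 0.0286 for P81S against wildtype and p = 0.1 for R167Q against wildtype, the smallest values these group sizes allow, and p = 0.171 for P81S against R167Q. Xist, the RNA of the inactive X chromosome and a mark of the female host's cells, was 7.44 ± 0.56 log2 (SD, n = 3) in wildtype, 7.48 ± 0.54 (SD, n = 4) in P81S and 8.26 ± 0.29 (SD, n = 3) in R167Q. Its exact permutation p was 0.857 for P81S against wildtype, 0.2 for R167Q against wildtype and 0.0857 for P81S against R167Q. After Benjamini-Hochberg adjustment over the 8 such tests, p for the Y-linked mean in P81S against wildtype was 0.229 by the exact permutation test, and the others were 0.267 or more.

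**Figure D2:**
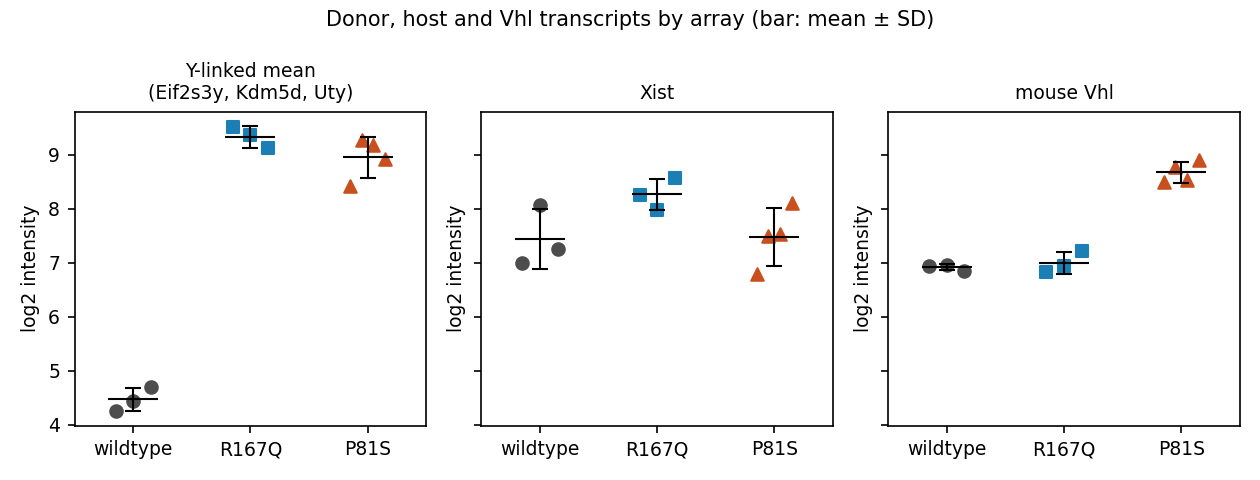
Log2 expression of mouse Vhl, the mean of 3 Y-linked transcripts and Xist in each array (points) with the group mean and SD, by genotype. The Y-linked mean was 4.26 to 4.70 in wildtype and 8.42 to 9.52 in the mutants, and Vhl was 8.49 to 8.90 in P81S and 6.83 to 7.21 elsewhere.

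Genes of chromosome 11 were lower in P81S replicates 1 and 2 than in the other arrays. Among the more highly expressed genes, set against the mean of wildtype and R167Q, the chromosome 11 median was -0.34 log2 in P81S replicate 1 and -0.35 in replicate 2, and 0.01 and -0.01 in replicates 3 and 4. Chromosome 8 medians were 0.16, 0.19, 0.15 and 0.16 log2 in P81S replicates 1 to 4. In the wildtype arrays they were -0.12, -0.02 and 0.08, and in R167Q 0.02, 0.03 and 0.03. The other 17 autosomes had medians between -0.08 and 0.09 log2 in every P81S array, and between -0.05 and 0.04 in the other arrays, apart from chromosome 6 at 0.10 in R167Q replicate 3. X chromosome medians were 0.10, 0.19, 0.05 and 0.09 log2 in P81S replicates 1 to 4, and -0.06 to 0.06 in the other arrays. Of the chromosome 8 genes, 28.8% were called higher and 11.9% lower in P81S than in the average of the other genotypes, and of the chromosome 11 genes 11% and 25.5%. Folds of single genes given below were not corrected for these shifts.

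**Figure D3:**
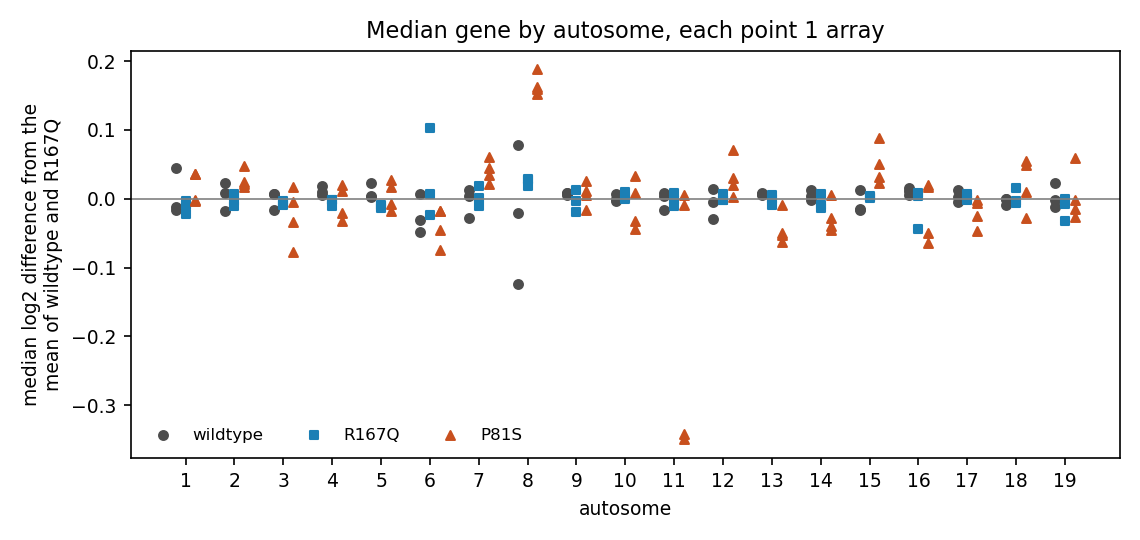
Median log2 difference of the more highly expressed genes of each autosome from the mean of wildtype and R167Q (vertical axis) by chromosome (horizontal axis), 1 point per array, coloured by genotype. Chromosome 11 stood at -0.34 and -0.35 in P81S replicates 1 and 2, and chromosome 8 at 0.15 to 0.19 in all 4 P81S arrays.

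The comparison of P81S with wildtype asks what the P81S form changes against the normal protein (4 against 3 arrays, errors as SE). Asz1, which acts in the piRNA pathway of germ cells, had the largest measured fall, 5.15 ± 0.38 on the log2 scale (35.6-fold), to a P81S mean of 4.68 log2, under the control block's median of 5.91. Usp26, a deubiquitinase gene of the testis, fell by 4.59 ± 0.35 (24-fold) and Dazl, an RNA-binding protein of germ cells, by 4.45 ± 0.45 (21.8-fold). Tktl1, a transketolase-like gene, was 17.2-fold lower (log2 -4.11 ± 0.27), and 1700018B24Rik, Zfp640, Ccdc152, Nlrp4c, Gm10324 and Fthl17e were 29.8-fold to 17.8-fold lower. Without P81S replicate 4, Zfp640 and Gm10324 were 14.1-fold and 11.9-fold lower, against 22.01-fold and 17.95-fold with it. Y-linked genes apart, Cga, the common alpha subunit of glycoprotein hormones, rose most, to 14.8-fold higher (log2 3.89 ± 0.60) and 9.28-fold without P81S replicate 4. Bpifa1, a secreted airway protein, was 10.4-fold higher (3.38 ± 0.68) and 6.73-fold without P81S replicate 1, Ntsr2, a neurotensin receptor, 10.3-fold (3.36 ± 0.34), Vgf, a neuropeptide precursor, 8.73-fold (3.13 ± 0.26), and Lcn2, an iron-siderophore carrier, 7.92-fold (2.99 ± 0.55). The antimicrobial lectin Reg3g rose 8.12-fold and Gm10419 rose 7.42-fold. Eif2s3y, Uty and Kdm5d were 30.3-fold, 24.2-fold and 15.3-fold higher, from wildtype means of 4.54, 4.21 and 4.65 log2.

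Mouse Vhl was 3.38-fold higher in P81S than in wildtype (log2 1.76 ± 0.15, adjusted p = 3.08e-05). In all, 6530 genes changed at an adjusted p under 0.05, 3230 higher and 3300 lower (3247 and 2990 with median centring), of which 1148 and 931 by at least 2-fold. The arrays of the groups did not overlap for 40.6% of all genes, against 5.71% by chance. Omission of any single array left 5073 to 6953 genes.

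Pluripotency genes fell together in P81S. Of 19 measured members 0 rose, 17 fell and 2 did not pass over all genes, and 0 rose and 17 fell when adjusted over the list alone. Dppa3, a maternal factor of the early embryo, fell by 4.10 ± 0.34 on the log2 scale (17.1-fold lower), Dppa4 by 3.18 ± 0.35 (9.06-fold) and Gdf3, a ligand of the TGF-beta family, by 2.72 ± 0.30 (6.60-fold). The list's mean difference was -2.58 log2 (adjusted p = 3.53e-10). Cell cycle genes fell as well: 30 of 31 over all genes and 31 adjusted over the list alone, with 0 higher, a mean of -1.46 log2 and adjusted p = 2.58e-13. Examples are the mitotic kinase gene Aurkb (log2 -1.46 ± 0.16, 2.74-fold lower), the G1 cyclin gene Ccne1 (-1.42 ± 0.17, 2.67-fold) and Mcm6 of the replicative helicase (-1.84 ± 0.23, 3.57-fold). Both calls were lost with an estimated correlation (adjusted p = 0.787 with an estimated correlation for each).

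Genes of the ATM DNA damage response, a pathway in the study's title, were lower in P81S. Of 40 measured, 1 rose, 29 fell and 10 did not pass, and 1 rose and 30 fell when adjusted over the list alone. Rad50, part of the complex that senses double-strand breaks, fell by 1.61 ± 0.16 on the log2 scale (3.04-fold lower), the checkpoint kinase gene Chek2 by 1.30 ± 0.14 (2.46-fold) and Xrcc5, the Ku80 subunit of end joining, by 1.20 ± 0.14 (2.29-fold). The mean was -0.89 log2 (adjusted p = 1.53e-10; adjusted p = 0.787 with an estimated correlation). Pluripotency and cell cycle genes were lower in the same arrays, with means of -2.58 and -1.46 log2.

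Apoptosis genes went both ways. Of 24 pro-apoptotic genes 3 rose, 2 fell and 19 did not pass, with the same 3 and 2 adjusted over the list alone (adjusted p = 0.553). Tnfrsf10b, a death receptor gene, was 2.62-fold lower (log2 -1.39 ± 0.18), Aifm1, a mitochondrial flavoprotein gene, 1.57-fold lower (-0.65 ± 0.12) and the kinase gene Dapk1 1.34-fold higher (0.43 ± 0.10). Of 17 anti-apoptotic genes 3 rose, 3 fell and 11 did not pass, again with 3 and 3 adjusted over the list alone (adjusted p = 0.894). Bcl2l1, which encodes BCL-XL, rose 1.59-fold (log2 0.67 ± 0.11) while Birc5, which encodes survivin and also acts in mitosis, fell 3.56-fold (-1.83 ± 0.20). Among 27 p53 targets 1 rose, 8 fell and 18 did not pass, with 1 and 8 adjusted over the list alone (mean -0.15 log2, camera adjusted p = 0.174). Fry, which tests a list without reference to the other genes, gave the p53 targets an adjusted p of 0.0451. The cell cycle inhibitor gene Cdkn1a was the member that rose, 2.09-fold (log2 1.06 ± 0.12), and Trp53inp1 fell 1.57-fold (-0.65 ± 0.12).

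Of 27 hypoxia-response genes 14 rose, 1 fell and 12 did not pass, with 14 and 1 adjusted over the list alone (mean 0.53 log2, adjusted p = 0.00389, and adjusted p = 0.787 with an estimated correlation). Vegfa, the endothelial growth factor gene, rose 2.83-fold (log2 1.5 ± 0.22), Egln1, an oxygen-sensing prolyl hydroxylase gene, 1.92-fold (0.94 ± 0.13) and the lipoprotein receptor gene Vldlr 1.92-fold (0.94 ± 0.14). Of 18 fatty acid oxidation genes 2 rose, 9 fell and 7 did not pass, with 2 and 10 adjusted over the list alone (mean -0.29 log2, adjusted p = 0.00434, and adjusted p = 0.787 with an estimated correlation). Acads and Etfa fell 1.93-fold and 1.73-fold while Ppargc1a, a coactivator of mitochondrial biogenesis, rose 2.71-fold. Of 47 oxidative phosphorylation genes 0 rose, 8 fell and 39 did not pass, with 6 lower adjusted over the list alone (mean -0.13 log2, adjusted p = 0.0181, and adjusted p = 0.804 with an estimated correlation). Its list call ended without P81S replicate 1 or wildtype replicate 1, at adjusted p of up to 0.105, and its mean in P81S replicate 4 (11.05 log2) lay within the wildtype range of 11.03 to 11.14. Of 20 glycolysis genes 6 rose and 2 fell, also adjusted over the list alone, and 12 did not pass (adjusted p = 0.196); Eno2, the neuronal enolase gene, was 4.47-fold higher, Hk1 2.06-fold and Pfkfb3 2.15-fold.

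Among tissue lists, the neural and glia lists passed higher and the yolk sac and liver list lower. Of 27 neural genes 15 rose, 2 fell and 10 did not pass, with 17 and 2 adjusted over the list alone (mean 0.66 log2, adjusted p = 0.000134, and adjusted p = 0.787 with an estimated correlation). Map2, a microtubule-associated protein gene of dendrites, rose 1.80-fold, the adhesion molecule gene Ncam1 1.78-fold and the growth cone gene Gap43 2.27-fold. Glia genes (4 of 16 higher, 0 lower, also adjusted over the list alone) had adjusted p = 0.0308, led by the astrocyte glutamate transporter gene Slc1a2 (4.33-fold higher) and Gfap (3.32-fold). Yolk sac and liver genes (0 of 22 higher, 6 lower, also adjusted over the list alone) had the same adjusted p = 0.0308, with the fibrinogen gene Fgb 4.21-fold lower. Their mean in P81S replicate 1, 7.70 log2, lay within the wildtype range of 7.17 to 7.71, and in the other P81S arrays it was 6.28 to 6.83. Interferon-response genes (2 of 27 higher, 8 lower, also adjusted over the list alone) had adjusted p = 0.0181, with the RNA sensor gene Ddx58 3.18-fold and Irf1 2.60-fold lower; their mean in P81S replicate 4, 7.98 log2, lay within the wildtype range of 7.71 to 8.09. The glia, yolk sac and liver, and interferon calls had adjusted p = 0.804 with an estimated correlation, and each ended with single arrays left out: glia without P81S replicate 3 or 4 or wildtype replicate 3 (up to 0.124), yolk sac and liver without P81S replicate 2 or 4 or wildtype replicate 2 (up to 0.137), and interferon without wildtype replicate 2 (0.128). They and the oxidative phosphorylation call also ended when dim genes were left out (up to 0.254). The glia call ended too with quantile normalization (0.0554), the replicate number as a block (0.0604) and without P81S replicates 3 and 4 (0.314), and the yolk sac and liver call with the block (0.0604) and without those replicates (0.132). Without P81S replicates 1 and 2 the interferon (0.0805) and oxidative phosphorylation (0.365) calls ended, and without the genes of chromosomes 8, 11 and Y the glia (0.0577) and interferon (0.0602) calls.

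The remaining 21 tested lists did not pass in this comparison, apoptosis, p53 targets and glycolysis among them. Higher and lower counts over all genes were 2 and 6 of 15 for trophoblast (adjusted p = 0.0575), in which the placental gene Tpbpa fell 4.61-fold and the homeobox gene Rhox9, of a multigene family, 11.3-fold. They were 6 and 0 of 24 for lipid and cholesterol synthesis, with the desaturase gene Scd1 2.10-fold higher, and 7 and 4 of 21 for NRF2 and oxidative stress, with the cystine transporter gene Slc7a11 3.58-fold higher. Both pairs of counts were the same adjusted over the list alone, as were those of the unfolded protein response (5 and 2 of 23), cartilage and bone (4 and 1 of 21), extracellular matrix (2 and 0 of 35), smooth muscle (1 and 0 of 14), adipocyte (1 and 0 of 13) and trophoblast. TCA cycle genes gave 3 and 4 of 21, and 3 and 5 adjusted over the list alone, with Suclg2 2.16-fold lower. Erythroid genes gave 3 and 0 of 11 (2 and 0 adjusted over the list alone), squamous epithelium 2 and 0 of 22 (1 and 0), skeletal and cardiac muscle 1 and 1 of 27 (0 and 1), endothelium 1 and 1 of 23 (0 and 0), gut and glandular epithelium 1 and 1 of 27 (0 and 0), mast cells 1 and 1 of 10 (0 and 1), macrophages 0 and 1 of 23 (0 and 0), and neutrophils and lymphocytes 0 and 2 of 20 (0 and 1). Of the 2 untested lists, the Y-linked list had 3 of 3 genes higher, also adjusted over the list alone, and Xist did not pass.

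**Figure D4:**
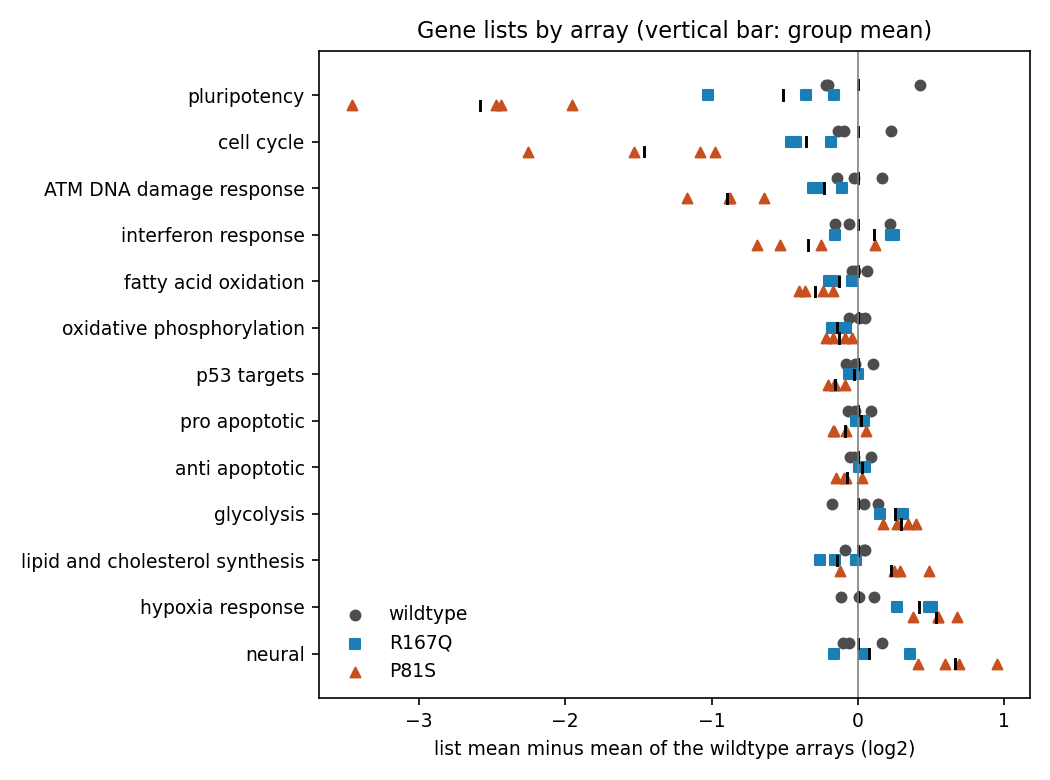
List mean of each array minus the mean of the wildtype arrays (log2, horizontal axis) for selected gene lists. Each point is 1 array, coloured by genotype, and a vertical bar marks the group mean. For P81S against wildtype the mean differences of the lists shown run from -2.58 for pluripotency to 0.66 for neural genes. With an estimated correlation 0 lists pass camera.

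The comparison of R167Q with wildtype asks the same of the other mutant (3 against 3 arrays, errors as SE). Among called genes not on the Y chromosome, Th and Nr4a2 rose most. Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, was 3.84-fold higher (log2 1.94 ± 0.29, adjusted p = 0.0441), and Nr4a2, a transcription factor of midbrain dopamine neurons, 3.57-fold (1.83 ± 0.24, adjusted p = 0.0195). Larger rises that did not pass included the erythroid genes Alas2 and Slc4a1 (7.03-fold and 5.79-fold, adjusted p = 0.300 and 0.329). The muscarinic receptor gene Chrm5 rose 2.84-fold (1.5 ± 0.15, adjusted p = 0.00365). Ret, the receptor of glial cell line-derived neurotrophic factor, and Shc3, a neuronal adaptor gene, rose 2.72-fold and 1.75-fold, and are named because they complete the calls, after their values were seen. The water channel gene Aqp8 fell by 1.69 ± 0.23 on the log2 scale (3.22-fold lower, adjusted p = 0.0215), the testis fatty acid-binding gene Fabp9 by 1.57 ± 0.17 (2.96-fold, adjusted p = 0.00699), Nup62cl by 1.32 ± 0.16, Prame by 1.14 ± 0.15 and Hesx1, a homeobox gene of the anterior embryo, by 1.01 ± 0.15.

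Vhl did not differ detectably in R167Q (log2 0.08 ± 0.16, adjusted p = 0.921). In all, 17 genes changed, 12 higher and 5 lower, and 7 of the 12 were Y-linked: Eif2s3y, Uty, Kdm5d, Uba1y, Zfy1, Zfy2 and Usp9y, 42.9-fold to 3.35-fold higher in measured values, over wildtype means of 4.02 to 5.56 log2 that lie under the control block's median of 5.91. At an unadjusted p under 0.05 there were 1832 genes, and the arrays of the groups did not overlap for 19.3% of genes against 10% by chance. The count fell to 5, 6 and 8 without wildtype replicates 1, 2 and 3 and to 8, 10 and 7 without R167Q replicates 1, 2 and 3, and 5 genes (Chrm5, Eif2s3y, Kdm5d, Uba1y and Uty) were called whichever array was left out. With Xist as a covariate only these 5 were called, and the other 12 calls ended (adjusted p of up to 0.422). Xist itself differed by 0.83 log2 in R167Q minus wildtype and by -0.78 in P81S minus R167Q. The covariate thus shares part of both contrasts. Calls of genes or lists lost with it do not show that host content accounts for them. Th, Nr4a2, Ret and Shc3 reached adjusted p of 0.237, 0.133, 0.117 and 0.271, Zfy1, Zfy2 and Usp9y of 0.0972, 0.262 and 0.127, and Aqp8, Fabp9, Nup62cl, Prame and Hesx1 of 0.149, 0.0622, 0.0933, 0.145 and 0.271, with single arrays left out.

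Hypoxia-response genes shifted upward as a list in R167Q, although none of the 27 passed over all genes. Adjusted over the list alone, 10 were higher and 0 lower, and the mean was 0.42 log2 (adjusted p = 4.50e-12, and adjusted p = 0.0666 with an estimated correlation). Vegfa was 2.09-fold higher at log2 1.07 ± 0.23 (adjusted p = 0.239), and Egln3 and Egln1, prolyl hydroxylase genes, stood at 0.68 ± 0.16 and 0.57 ± 0.14 (adjusted p = 0.283 for each). Glycolysis genes had a mean of 0.25 log2 (adjusted p = 5.95e-07, and adjusted p = 0.459 with an estimated correlation), with 4 of 20 higher adjusted over the list alone and 0 over all genes. Its members Pfkl, Pfkfb3 and Tpi1 stood at 0.50 ± 0.12, 0.69 ± 0.18 and 0.40 ± 0.11 log2, at adjusted p of 0.283, 0.300 and 0.323. Oxidative phosphorylation genes had a mean of -0.14 log2 (adjusted p = 9.69e-07, and adjusted p = 0.532 with an estimated correlation), with 0 of 47 called over all genes or adjusted over the list alone.

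In total 18 of 31 lists passed in R167Q against wildtype, while 0 members of any tested list were called over all genes. Host and mesenchymal lists were higher: macrophage (mean 0.38 log2, adjusted p = 2.42e-07), endothelium (0.60, 1.28e-06), smooth muscle (0.50, 0.000388), extracellular matrix (0.28, 0.000437), cartilage and bone (0.24, 0.00267) and skeletal and cardiac muscle (0.43, 0.00287), with 0 members passing adjusted over the list alone (adjusted p = 0.349 to 0.698 with an estimated correlation). Erythroid, glia and adipocyte genes had means of 0.89, 0.30 and 0.36 log2 (adjusted p = 0.000510, 0.00375 and 0.0130), with 3, 2 and 1 members higher adjusted over the list alone (adjusted p = 0.349, 0.629 and 0.629 with an estimated correlation). Cell cycle, ATM response, pluripotency and fatty acid oxidation genes had means of -0.35, -0.23, -0.51 and -0.13 log2 (adjusted p = 5.25e-05, 7.87e-05, 0.00150 and 0.00634), with 0 members passing adjusted over the list alone (adjusted p = 0.595 to 0.676 with an estimated correlation). TCA cycle and yolk sac and liver genes had means of -0.11 and -0.43 log2 (adjusted p = 0.00335 and 0.00364), with 1 and 3 lower adjusted over the list alone (adjusted p = 0.532 and 0.629 with an estimated correlation). Xist, a mark of host cells, was 0.83 ± 0.34 log2 in R167Q minus wildtype (adjusted p = 0.481).

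Several of these list calls ended with single arrays left out. Without R167Q replicate 1 or wildtype replicate 3, muscle genes reached adjusted p of up to 0.982, and without wildtype replicate 3 or R167Q replicate 2, pluripotency and glia genes reached up to 0.231. Adipocyte genes reached up to 0.368 without wildtype replicate 1 or R167Q replicate 1, cartilage and bone 0.0520 without R167Q replicate 1, fatty acid oxidation 0.0652 without wildtype replicate 1, and yolk sac and liver 0.111 without wildtype replicate 2. Without dim genes the muscle (0.0539), cartilage and bone, and yolk sac and liver calls (0.192 for each) ended. With Xist as a covariate, the pluripotency, adipocyte, cartilage, fatty acid oxidation, glia, TCA cycle and yolk sac calls ended, and the cell cycle mean was 0.04 log2 (adjusted p = 0.666). The other 13 lists, pro-apoptotic genes (adjusted p = 0.766), anti-apoptotic genes (0.480) and p53 targets (0.751) among them, did not pass, with 0 members called over all genes or adjusted over the list alone.

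All 10 non-Y-linked genes called in R167Q against wildtype were called in the same direction in P81S against wildtype. For 10 shared higher calls and 5 shared lower calls, Y-linked ones included, independent lists would share 2.06 and 0.877. Across genes, which are not independent replicates, the 2 mutants' differences from wildtype correlated with r = 0.696, against 0.534 in 100 simulations of unchanged groups with the same controls, and had the same sign for 75.6% of genes against 67.9%. The covariance was 0.128 against 0.0280 simulated, a difference of 0.1. Genes were simulated independently of each other, unlike the correlated genes of the data. The simulations therefore do not show how far these measures vary by chance with shared controls. With 3 wildtype arrays the controls could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

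The direct comparison of P81S with R167Q asks how the 2 mutants differ (4 against 3 arrays, errors as SE). Several genes with the largest rises in P81S encode forebrain regulators. A forebrain list, chosen only after these values were seen, is given under other observations. Dlx1, Dlx5 and Dlx2, homeobox genes of the interneurons of the ventral forebrain, rose 6.87-fold (log2 2.78 ± 0.36), 5.21-fold (2.38 ± 0.27) and 4.54-fold (2.18 ± 0.34), Nkx2-1, a homeobox gene of ventral forebrain, lung and thyroid, 5.51-fold (2.46 ± 0.49) and Fezf2, a transcription factor of forebrain neurons, 4.38-fold (2.13 ± 0.43). Cga was 13.7-fold higher (3.78 ± 0.60) and 8.60-fold without P81S replicate 4, Bpifa1 7.89-fold (2.98 ± 0.68) and 5.09-fold without P81S replicate 1, and Reg3g, Barhl2 and Trpc5 4.37-fold to 4.04-fold. The germ cell genes Asz1, Dazl and Usp26 were 19-fold, 15.8-fold and 15.2-fold lower (log2 -4.25 ± 0.38, -3.98 ± 0.45 and -3.92 ± 0.35). The pluripotent cell genes Dppa5a and Fbxo15 were 9.63-fold and 9.50-fold lower, Dppa5a 5.82-fold without P81S replicate 4.

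Vhl was 3.21-fold higher in P81S than in R167Q (log2 1.68 ± 0.15, adjusted p = 0.000333). In all, 4234 genes changed, 2333 higher and 1901 lower (2541 and 1467 with median centring), of which 629 and 495 by at least 2-fold, and the arrays did not overlap for 30.7% of genes against 5.71% by chance. The count was 2328 without R167Q replicate 1, and 2419 without P81S replicates 3 and 4, an omission chosen after the data were seen. The calls of Bpifa1 and Reg3g ended with single arrays left out: for Bpifa1 without R167Q replicate 1 (adjusted p = 0.0520), and for Reg3g without P81S replicate 3, R167Q replicate 1 or R167Q replicate 2 (up to 0.118). With Xist as a covariate the calls of Fezf2, Bpifa1 and Reg3g ended (0.0581, 0.0911 and 0.141), and that of Reg3g also ended with the replicate number as a block (0.0637), with only the compared groups in the model (0.0589) and without P81S replicates 3 and 4 (0.0606). The Y-linked genes Uba1y, Zfy1, Zfy2, Usp9y and Sly, named after their values were seen, differed from R167Q by -2.37, -2.67, -2.89, -1.51 and -1.13 log2 (adjusted p = 0.00101, 0.00254, 0.00115, 0.00116 and 0.00379). In P81S, Zfy1, Zfy2, Usp9y and Sly had means of 5.63, 5.23, 4.26 and 4.70 log2, under the control block's median of 5.91. Usp9y and Sly lay under it in R167Q too (5.76 and 5.83).

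Pluripotency, cell cycle and ATM response genes were lower in P81S than in R167Q too. For pluripotency 0 rose and 17 of 19 fell, also adjusted over the list alone (mean -2.07 log2, adjusted p = 9.35e-12), with Dppa3 9.32-fold lower, the core factor gene Nanog 8.15-fold (log2 -3.03 ± 0.43) and Dppa4 5.34-fold. For the cell cycle 0 rose and 29 of 31 fell, and 30 adjusted over the list alone (mean -1.11 log2, adjusted p = 2.54e-14), with Aurkb 2.17-fold lower and the transcription factor gene E2f1 1.92-fold. For the ATM response 1 of 40 rose and 24 fell, and 1 and 27 adjusted over the list alone (mean -0.66 log2, adjusted p = 5.98e-11), with Rad50 2.48-fold lower and Brca1, a homologous recombination gene, 3.02-fold (-1.59 ± 0.24). The 3 calls had adjusted p = 0.881 with an estimated correlation.

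The neural and lipid synthesis lists passed higher in P81S than in R167Q. Of 27 neural genes 14 rose and 0 fell, also adjusted over the list alone (mean 0.58 log2, adjusted p = 7.52e-05, and adjusted p = 0.881 with an estimated correlation), Dlx1, Dlx2 and Ncam1 (1.51-fold) among them. Of 24 lipid and cholesterol synthesis genes 10 rose and 0 fell, also adjusted over the list alone (mean 0.37 log2, adjusted p = 0.000780, and adjusted p = 0.923 with an estimated correlation). The desaturase genes Scd1 and Scd2 rose 1.99-fold and 1.28-fold and the methylsterol monooxygenase gene Msmo1 1.78-fold. Interferon-response genes had 0 higher and 6 of 27 lower, also adjusted over the list alone (mean -0.45 log2, adjusted p = 0.000176, and adjusted p = 0.923 with an estimated correlation), with Ddx58 2.48-fold and Irf1 2.14-fold lower. The lipid and interferon calls ended with Xist as a covariate, and the means of P81S replicate 4, 9.68 and 7.98 log2, lay within the R167Q ranges of 9.54 to 9.78 and 7.71 to 8.12.

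Fatty acid oxidation genes had 1 higher and 7 of 18 lower, also adjusted over the list alone (mean -0.16 log2, adjusted p = 0.0145, and adjusted p = 0.881 with an estimated correlation), with Etfa and Acads 1.44-fold and 1.54-fold lower and Ppargc1a 2.40-fold higher. This call ended without R167Q replicate 2 (adjusted p = 0.0749). Trophoblast genes had 1 higher and 4 of 15 lower, also adjusted over the list alone (mean -0.61 log2, adjusted p = 0.0257, and adjusted p = 0.881 with an estimated correlation), with Tpbpa 8.31-fold and Rhox9 7.64-fold lower, and their call ended without R167Q replicate 2 (0.0614), with the replicate number as a block (0.0535) and without P81S replicates 3 and 4 (0.0509). Macrophage genes had 0 higher and 2 of 23 lower, and 1 lower adjusted over the list alone (mean -0.27 log2, adjusted p = 0.0257, and adjusted p = 0.966 with an estimated correlation), and their call ended without P81S replicate 2 or 3 or R167Q replicate 2 or 3 (up to 0.244), with Xist as a covariate (0.230) and without P81S replicates 1 and 2 (0.0740). In total 9 of 31 lists passed, and 14 without P81S replicate 1.

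Hypoxia and apoptosis lists did not pass between the mutants. Of 27 hypoxia-response genes 0 were higher and 1, the chemokine receptor gene Cxcr4, lower (1.41-fold), with 0 adjusted over the list alone (mean 0.11 log2, adjusted p = 0.916). The Cxcr4 call (adjusted p = 0.0197) ended without R167Q replicate 1 or 3 (0.0896 and 0.0545), with the replicate number as a block (0.0518) and without P81S replicates 3 and 4 (0.0857). Pro-apoptotic genes had 2 higher and 2 lower of 24 (adjusted p = 0.518), anti-apoptotic genes 1 higher and 2 lower of 17 (0.670) and p53 targets 1 higher and 3 lower of 27 (0.180), each also adjusted over the list alone. Tnfrsf10b was 2.17-fold and Birc5 2.79-fold lower, and Cdkn1a 1.58-fold higher. Glycolysis genes had 3 higher and 4 lower of 20, also adjusted over the list alone (adjusted p = 0.662), and their mean (0.04 log2) and median (-0.06) differed in sign. Oxidative phosphorylation genes had 0 of 47 called, also adjusted over the list alone, and a mean of 0.01 log2 while the test pointed lower (adjusted p = 0.916).

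The comparison of P81S with the average of wildtype and R167Q follows the labels' division into apoptosis-resistant and apoptotic tumours (4 against 6 arrays, errors as SE). Cga was 14.2-fold higher in P81S (log2 3.83 ± 0.51; 8.93-fold without P81S replicate 4), Ntsr2 6.43-fold (2.69 ± 0.28), Dlx1 5.62-fold (2.49 ± 0.30), Nkx2-1 5.26-fold (2.40 ± 0.41), Vgf 5.18-fold (2.37 ± 0.22) and Gabrq, a GABA receptor subunit gene, 4.65-fold (2.22 ± 0.15). The germ cell genes Asz1, Usp26 and Dazl were 26.0-fold, 19-fold and 18.5-fold lower (log2 -4.70 ± 0.32, -4.25 ± 0.30 and -4.21 ± 0.38) and Dppa3 12.6-fold (-3.66 ± 0.29). Vhl was 3.29-fold higher (1.72 ± 0.13, adjusted p = 1.83e-05).

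In all, 6713 genes changed, 3447 higher and 3266 lower (3621 and 2820 with median centring), of which 894 and 705 by at least 2-fold. The arrays did not overlap for 26.4% of genes, against 0.952% by chance, and omission of any single array left 5736 to 7038 genes. Pro-apoptotic genes had 2 higher and 2 lower of 24 and anti-apoptotic genes 3 higher and 3 lower of 17, each also adjusted over the list alone (adjusted p = 0.616 and 0.848). The p53 targets had 1 higher and 6 lower of 27, and 1 and 5 adjusted over the list alone (camera adjusted p = 0.173, fry adjusted p = 0.0361). Birc5 was 3.15-fold lower (log2 -1.66 ± 0.17), Tnfrsf10b 2.39-fold lower (-1.25 ± 0.15), Bcl2l1 1.45-fold higher (0.54 ± 0.09) and Cdkn1a 1.82-fold higher (0.86 ± 0.10).

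Of 31 lists 8 passed in this comparison. Cell cycle genes were lower in 31 of 31, also adjusted over the list alone (mean -1.28 log2, adjusted p = 5.84e-14), pluripotency genes in 17 of 19, also adjusted over the list alone (-2.33, 8.11e-11), and ATM response genes in 28 of 40 with 1 higher, and 30 with 1 higher adjusted over the list alone (-0.78, 8.11e-11). With an estimated correlation these 3 lists had adjusted p = 0.828, as had fatty acid oxidation (2 higher and 8 lower of 18, also adjusted over the list alone, -0.23 log2, adjusted p = 0.00562) and trophoblast genes (1 higher and 5 lower of 15, and 2 and 7 adjusted over the list alone, -0.64 log2, adjusted p = 0.0442). Neural genes had 15 higher and 2 lower of 27, and 16 and 2 adjusted over the list alone (0.62 log2, adjusted p = 9.90e-05, and adjusted p = 0.889 with an estimated correlation). Lipid synthesis genes had 11 higher and 0 lower of 24, and 12 adjusted over the list alone (0.30 log2, adjusted p = 0.0122), and interferon-response genes 2 higher and 10 lower of 27, and 2 and 11 adjusted over the list alone (-0.39 log2, adjusted p = 0.00243), both at adjusted p = 0.966 with an estimated correlation. The trophoblast call ended without P81S replicate 4 or R167Q replicate 2 (up to 0.0672) and the lipid call without P81S replicate 2 (0.0515). The trophoblast call also ended with quantile normalization (0.0594), the replicate number as a block (0.0735) and without P81S replicates 3 and 4 (0.0771), and reached adjusted p = 0.0630 without the genes of chromosomes 8, 11 and Y. The lipid call ended with Xist as a covariate (0.0550) and without P81S replicates 1 and 2 (0.154), and the interferon call when dim genes were left out (0.130).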

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

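None of the tests in this part was chosen after its result was seen. Among the 4 P81S arrays, 79 values (named genes, some of them picked from the data, and list means) were examined for a sample set apart from the other 3, and 3 of them, 3.80%, had one, where chance gives about 1 in 20. Tktl1 was 6.31 log2 in P81S replicate 2 against 5.16 to 5.27 in the others. Vgf was 10.08 log2 in P81S replicate 1 against 9.77 to 9.78. The mean of the trophoblast list was 5.21 log2 in P81S replicate 4 against 5.50 to 5.56.

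Probe sets left out of the gene tests also differed between genotypes when tested with limma together with all others. Of the 1881 probe sets paired with several genes, 567 were called in P81S against wildtype, 360 in P81S against R167Q and 593 in P81S against the average of the other genotypes (30.1%, 19.14% and 31.5%). Of the 5845 with no listed gene, 997, 570 and 1045 were called in the same comparisons (17.1%, 9.75% and 17.9%), and 2 in R167Q against wildtype. In the array's control block of 6612 probe sets the same shares were 8.33%, 3.92% and 9.76%, and 0 were called in R167Q against wildtype.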

How the results depend on the processing

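The tests without the genes of chromosomes 8, 11 and Y and without pairs of P81S arrays were chosen only after the data were seen. Of the recomputed gene counts 91 stayed within 1.5 times the reported count and 14 did not, and of the list counts 74 and 8. All 104 values of host and donor transcripts moved by less than the SD of the compared arrays. That limit is wide. Xist in P81S minus wildtype ran from -0.17 to 0.36 log2 without single arrays and stayed within it. For R167Q against wildtype, 17 genes became 9 without dim genes (fewer genes tested), 38 over all probe sets, 26 with only the compared groups in the model, 42 with array weights, 5 with Xist as a covariate and 7 without the 3 chromosomes; without single arrays the count ran from 5 to 21. For P81S against R167Q, 4234 genes became 2419 without P81S replicates 3 and 4 and ran from 2328 to 4916 without single arrays, and its passing lists from 7 to 14. With an estimated correlation 0 lists passed in each of the 4 comparisons. With fry, which tests a list without reference to the other genes, 1 passed in R167Q against wildtype and 3 in P81S against R167Q. In P81S against wildtype and in P81S against the average, 8 lists each passed with fry. In both these were the pluripotency, cell cycle, ATM response, fatty acid oxidation, hypoxia, neural, trophoblast and p53 lists. Without dim genes 6 lists passed in P81S against wildtype. The cell cycle list in R167Q against wildtype turned to 0.0398 log2 with Xist as a covariate (adjusted p = 0.666). Apart from the counts made from fewer genes or arrays, the cause was not tested.

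With the replicate number as a replicate block, the 4 gene counts were 5368, 15, 2952 and 5263, and Xist in P81S minus R167Q was -0.99 log2 (adjusted p = 0.0454) against -0.78 without it (0.104); without single arrays it ran from -0.99 to -0.55. Deviations of arrays with the same number correlated at r of -0.28 to 0.21, and 1 of 9 arrays correlated best with an array of their own number, so the numbers were not taken to pair samples. The 3 possible pairings of P81S clones as a random block gave 6437, 7081 and 6608 genes for P81S against wildtype. Of 450 named results 292 passed and 229 of these passed under every alternative. An alternative based on probe set name endings was not run, because the probe sets have numeric names, and a model of only the compared groups does not apply to P81S against the average. Without dim genes 26 lists could be tested. Signal over background is unknown here, so how far dim genes limit these counts was not measured.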

Other observations

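The germline, forebrain, hindbrain and dopaminergic lists, and the tests on Y-linked genes, gene density and the share of lower chromosome 11 genes between arrays, were chosen only after the results they bear on were seen. Germ cell genes fell as a group in P81S against the average of the other genotypes: of 34 measured genes 0 rose and 30 fell, and 31 adjusted over the list alone, with a mean of -2.06 log2 (adjusted p = 3.45e-19 over 35 lists, and adjusted p = 0.668 with an estimated correlation). The difference was -3.64 ± 0.33 log2 for the meiotic regulator Meioc, -3.25 ± 0.23 for the meiotic cohesin gene Smc1b, and -2.88 ± 0.23 and -2.39 ± 0.25 for the synaptonemal complex genes Sycp1 and Sycp3 (SE, 4 against 6 arrays). Without Asz1 and Dazl, which had drawn attention to the list, the other 32 genes gave a mean of -1.91 log2 with 28 lower and adjusted p = 9.21e-18 (adjusted p = 0.644 with an estimated correlation). Pluripotency and cell cycle genes fell in the same comparison (means of -2.33 and -1.28 log2), and many germ cell genes are also active in pluripotent cells, so a fall of germ cells apart from pluripotent ones was not shown.

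Forebrain and hindbrain lists were examined in P81S against R167Q, without a test of the lists against each other. Of 28 forebrain and GABAergic genes 21 rose and 1, Hesx1, fell, and 22 and 1 adjusted over the list alone, with a mean of 1.28 log2 (adjusted p = 1.63e-10, and adjusted p = 0.5 with an estimated correlation), among them Gad1, a GABA-synthesising enzyme gene (1.94 ± 0.33), and Six3 (1.67 ± 0.24). The 22 genes not already named from the data had a mean of 1.13 log2 (adjusted p = 3.59e-09, and 0.464 with an estimated correlation). Of 21 hindbrain and spinal cord genes 0 rose and 4 fell, and 2 adjusted over the list alone (mean -0.38 log2, adjusted p = 0.00275, and adjusted p = 0.740 with an estimated correlation), Hoxb1 at -1.50 ± 0.26 among them. A more forebrain-like identity of the neural tissue in P81S than in R167Q teratomas is a candidate explanation. Whole tumours were measured, and pluripotency genes fell in the same comparison (mean -2.07 log2). The values therefore do not place the forebrain rise or the hindbrain fall in neural tissue. Against wildtype the forebrain list passed too (mean 1.11 log2, adjusted p = 2.15e-06, and adjusted p = 0.616 with an estimated correlation), but the hindbrain list did not (adjusted p = 0.0667), and Hesx1, of the anterior embryo, fell in both comparisons. In R167Q against wildtype, 18 dopaminergic neuron genes had a mean of 0.92 log2 with 3 higher, and 7 adjusted over the list alone (adjusted p = 2.99e-10, and adjusted p = 0.406 with an estimated correlation). The 15 without Th, Nr4a2 and Ret had a mean of 0.76 log2 and adjusted p = 1.17e-05 (0.468 with an estimated correlation) with 0 called singly. Their values were uneven. The dopamine transporter gene Slc6a3 stood at 2.78 ± 0.47 (adjusted p = 0.0841) and Chrna6 at 2.40 ± 0.41. Ddc and Slc18a2 stood at 0.17 and 0.006 log2, and Gch1 and En2 at -0.32 and -0.50. The list was also higher in P81S than in wildtype (mean 0.85 log2, 9 higher, adjusted p = 0.0268, and adjusted p = 0.773 with an estimated correlation) and did not pass between the mutants (mean -0.07 log2, adjusted p = 0.825), so both mutants differed from the same 3 wildtype arrays.

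Y-linked transcripts were low in the 3 wildtype teratomas. More female host tissue in them would dilute donor transcripts, yet the pluripotency list's median was higher in wildtype than in R167Q, by 0.53 log2 (quartiles 0.42 to 0.69, 19 genes). A swap of single wildtype and mutant arrays would need mutant arrays with low Y-linked means, of which there were 0. An exchange of the whole wildtype group with a mutant group would leave 0 as well and stays open as a question of labels. Either would only move the low values to another genotype of the same male J1 cells. Neither therefore accounts for low Y-linked transcripts in 3 teratomas. Absence of a Y chromosome from the cells that formed the wildtype teratomas may account for the pattern and stays open too. Apart from the 3 genes that showed it, only 1 Y-linked gene, Uba1y, was above 7 log2 in both mutants. It was 1.79 log2 lower in wildtype. Zfy1 and Zfy2 were above 7 log2 in R167Q alone (means of 8.30 and 8.12). Their means were 4.31 and 5.21 log2 in wildtype, but also 5.63 and 5.23 in P81S, where other Y-linked transcripts were high. The lower Zfy1 and Zfy2 in P81S than in R167Q (-2.67 and -2.89 log2) were left unexplained.

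The shifts of chromosomes 11 and 8 ran along their length, by limits set once the shifts but not the bins had been seen: in P81S replicates 1 and 2, 10 of 10 consecutive bins of chromosome 11 genes had a median below -0.15 log2, and in all 4 P81S arrays at least 9 of 10 bins of chromosome 8 genes had one above 0.08 log2, against 5 in wildtype replicate 3 and 0 or 1 in the other arrays. A trend with gene density was argued against by the 3 autosomes nearest in density, which fell by at most 0.0714 of the chromosome 11 shift. Different tissue makeup was argued against because, between single arrays, at least 82.1% of chromosome 11 genes were lower in replicate 1 or 2 than in 3 or 4, and at most 53.7% on any other autosome; this comparison was recast by pairs of arrays after the averages had been seen. A change in copy number of these chromosomes in the cells, whole or in part of them, is a candidate explanation for both shifts, with ratios of 0.789 and 0.785 for chromosome 11 and 1.11 to 1.14 for chromosome 8, though the wildtype arrays themselves ran from -0.124 to 0.0777 log2 on chromosome 8 and the X chromosome, not tested in bins, stood at 0.19 log2 in P81S replicate 2. The labels name 2 P81S clones without saying which arrays share one, so whether the chromosome 11 shift belongs to a clone was not tested.

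Pluripotency, cell cycle and ATM response genes fell together in P81S. Genes of chromosomes 8, 11 and Y did not carry this, since all 3 lists passed without them, with means of -2.28, -1.26 and -0.76 log2, though with an estimated correlation the 3 calls were lost with or without them (adjusted p = 0.890 without, 0.828 with). Without those genes 2 other list calls of P81S against wildtype, glia and interferon, and 1 against the average, trophoblast, ended. A smaller share of undifferentiated, dividing cells in P81S teratomas may account for it: as deviations from group means over the 10 arrays, cell cycle and pluripotency means correlated with r = 0.851 (permutation p = 0.0139) and rho = 0.842 (permutation p = 0.00814), and with r = 0.691 without P81S replicate 4 and R167Q replicate 2, the arrays farthest from the median, in the 1 such relation computed. A direct effect of the P81S protein on the ATM response genes stays open and untested in bulk tissue.

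Other splits of the arrays were refitted for each gene count. For P81S against wildtype 1 of 35 splits, the real one, gave as many as 6530 genes and the highest other gave 2719. For P81S against R167Q 1 of 35 gave 4234 and the highest other 1751. For P81S against the average 1 of 100 drawn gave 6713 and the highest other 1861. These are the smallest shares such splits can give. They set the 3 counts apart from other divisions of these arrays. Because P81S arrays share clones, they cannot exclude a chance difference between a few clones. For R167Q against wildtype, 1 of 10 splits gave 17 genes and the highest other 0, and 10 splits are too few for a share under 0.05.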
